A study of Mus musculus with 12 samples.

How the data were processed

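RNA sequencing measured gene expression in 12 lines of Ba/F3 cells, 4 biologically independent lines each of 3 groups per the labels. Ba/F3 is a mouse pro-B line that depends on interleukin-3. The MSCV lines carried the empty retroviral vector and grew with 0.5 ng/ml IL-3, and the BCR-ABL1 and SFPQ-ABL1 lines carried a fusion of the ABL1 tyrosine kinase and grew without IL-3. Per the labels, cells were washed, pelleted and snap frozen, and total RNA was extracted with the PureLink RNA Mini Kit and made into libraries by Illumina protocols. Reads were aligned and counted with Subread and featureCounts on mm10, per the submitters' processing notes. Their versions, the annotation release, the use of strand and the treatment of reads with several matches are not given in the sources used here. The authors deposited raw counts per Ensembl gene and raw counts per Ensembl exon, with no normalization, and all results were computed from those counts.

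Gene totals per library ran from 59355018 to 80616227 counts, so a level of 1 CPM stood for 59.4 to 80.6 counts. Counts are PCR reads without molecular identifiers, so intervals made from them cover counting error only. The exon totals were 18.0% of the gene totals. In genes with a single exon the exon held a median of 8.29% of the gene count, so the exon table holds a subset of the reads that the sources used here do not describe. Exons with the same coordinates on opposite strands had identical counts in 6 of 6 pairs. Overlapping and antisense genes may therefore share reads in that table, and the same cannot be ruled out for the gene table. Gene symbols, biotypes and coordinates came from GENCODE release M21 on mm10. It held 55230 of the 55471 gene identifiers and 524704 of the 527754 exon identifiers. Genes without an entry kept their identifiers, and exons without one were left out. Exons repeating the coordinates of another exon of the same gene were also left out, which left 447909. Exons shared by different genes were kept, so reads on them count for each of these genes.

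Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr, which left 17197, and libraries were scaled by TMM factors. The quasi-likelihood test (glmQLFit and glmQLFTest) was fitted to all 12 libraries with group as the only term, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a single gene comes from this two-sided test unless another tool is named. CPM in the text are TMM-scaled for genes. For exons they are exon counts scaled by the gene totals of the libraries, without TMM factors. Both are given as mean ± SD of 4 lines. The comparisons were BCR-ABL1 against MSCV, SFPQ-ABL1 against MSCV and SFPQ-ABL1 against BCR-ABL1. Only the last is free of the difference in IL-3. Replicates of a group were compared by chi-square tests over genes with at least 50 summed counts, and the 18 pairs had 33.1 to 182 per degree of freedom, so no pair agreed within sampling noise.

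The groups, the tests, 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered STAT5 and IL-3 response, ERK output, pro-survival and pro-death BCL-2 family, FOXO, NF-kB, interferon, p53, cholesterol, glycolysis, oxidative phosphorylation, ATF4 and amino acid response, S phase, G2 and mitosis, ribosome biogenesis, paraspeckles, ABL adaptors with Src-family kinases, cytokine receptors with JAK-STAT, cytokines, adhesion, and genes of early B, granulocyte, mast, T and NK, erythroid and stromal cells. Each list was tested against the other genes with camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry. Named genes were, per comparison, the 12 largest rises and 12 largest falls among called protein-coding genes with at least 5 CPM in the higher group and no overlap between the lines of both groups. Immunoglobulin and T cell receptor segments and genes known only by a predicted or clone name were passed over. Up to 4 members of each list with the smallest adjusted p were also named, with Abl1, Bcr and Sfpq, and, for exon usage, the 10 genes with the smallest p. Psph, and Il2rb in the comparison with MSCV, are named outside this rule. Exon usage was tested with diffSpliceDGE on exons passing filterByExpr, by the Simes p of each gene.

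For the overlap of both comparisons with MSCV, all 12 libraries, the controls included, were simulated 20 times from the MSCV means without any change. The edgeR gene test, the list tests, the covariance of both comparisons with MSCV and the edgeR exon usage test were first run on simulated data with known changes. Genes were drawn independently there, so these runs could not show an effect of correlation between the genes of a list. The other tools and the tests of technical explanations were not run on simulated data. The gene test recovered 64.2% of genes changed 2-fold for BCR-ABL1 against MSCV (11 of 132 calls false among 16972 genes), 55.2% for SFPQ-ABL1 against MSCV (4 of 115 among 16951) and 59.7% between the fusions (11 of 123 among 16941). For changes of 1.5-fold it recovered 37.3%, 31.3% and 26.9% in the same order. The exon usage test recovered 12, 14 and 16 of 100 genes with a 2-fold change of an exon, and 97, 86 and 87 with a 4-fold change, among 9750, 9751 and 9752 genes.

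The alternatives were upper-quartile factors, no factors, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 1 CPM in 4 libraries, the 8 libraries compared, the replicate number as a block, a test against a fold change of 1.5, and each library left out in turn. For exons they were the gene-level F test, limma diffSplice and a filter of 20 counts in 4 libraries. Chosen after seeing the data were a fit without SFPQ-ABL1 line 2 and BCR-ABL1 line 4, and a fit with the counts of processed pseudogenes added to their parent genes. Parents were found with BLAST 2.17.0 at 85% identity or more. The 6282 pseudogenes with a single best parent held 10.3% of all gene counts. For 216 parents, counted only above a minimum of combined counts, more than 50% of these counts lay on the pseudogenes, among them Fdps, Idi1, Npm1, Gapdh, Pgam1, Phgdh, Pcna, Hnrnpa1 and Nudt21. Their values are uncertain, as are those of genes with close paralogs (the Bcl2a1 copies, Acat2, Ctla2a, Gsta3, Mettl7a1, Serpina3g and Slco1a5). The figures were drawn with matplotlib 3.10.9. The reads themselves were not analysed here. Some results for genes that the rule picked are not reported here.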

Results

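Gene expression was measured by RNA sequencing of total RNA from Ba/F3 cells, a mouse pro-B cell line that needs interleukin-3 (IL-3) to survive and divide unless an oncogene replaces that signal. The 12 libraries came from 3 groups of 4 biologically independent lines. One group carried the empty MSCV retroviral vector and grew with 0.5 ng/ml IL-3. The others carried BCR-ABL1 or SFPQ-ABL1, fusions of the ABL1 tyrosine kinase found in acute lymphoblastic leukaemia, and grew without IL-3. Total gene counts ran from 59355018 in SFPQ-ABL1 line 4 to 80616227 in SFPQ-ABL1 line 3. Exon counts ran from 10061439 to 15560875 in the same lines. The gene counts were 79316348, 75668465, 76355410 and 66040297 in MSCV lines 1 to 4. They were 73256723, 73792854, 68635709 and 66966842 in BCR-ABL1 lines 1 to 4, and 71359372 and 75685317 in SFPQ-ABL1 lines 1 and 2. The first principal component held 40.3% of the variance and placed all 4 BCR-ABL1 lines on one side and the 8 other lines on the opposite side. The mean root-mean-square log2 difference between libraries was 0.89 between MSCV and BCR-ABL1 and 0.89 between BCR-ABL1 and SFPQ-ABL1. It was 0.69 between MSCV and SFPQ-ABL1, against 0.59, 0.57 and 0.62 within the MSCV, BCR-ABL1 and SFPQ-ABL1 groups.

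The genes that make up the fusions served as a check of the labels. The fusions are assumed to be human cDNAs whose reads align in part to the mouse genes, so counts on these exons can hold reads of a fusion beside those of the mouse gene. Exon 9 of Abl1 (chromosome 2, 31796973 to 31797062, mm10) encodes part of ABL1 that both fusions hold. This exon had 0.0503 ± 0.00340 CPM (exon counts scaled by the gene totals, mean ± SD, n = 4 lines) with MSCV. It reached 13.3 ± 5.14 with BCR-ABL1 and 17.5 ± 9.50 with SFPQ-ABL1. Exon 3 of Abl1 (31778921 to 31779216) was at 3.47 ± 0.853 CPM with BCR-ABL1, 0.318 ± 0.114 with MSCV and 0.303 ± 0.0854 with SFPQ-ABL1. Exon 1 of Bcr (chromosome 10, 75060592 to 75062310) was at 2.04 ± 0.653 CPM with BCR-ABL1, 0.122 ± 0.0381 with MSCV and 0.158 ± 0.106 with SFPQ-ABL1. Exon 9 of Sfpq (chromosome 4, 127027397 to 127027518) was at 14.0 ± 6.79 CPM with SFPQ-ABL1, 1.84 ± 0.243 with MSCV and 2.25 ± 0.919 with BCR-ABL1. Exon 10 of Sfpq, the last of the same transcript (127029827 to 127031236), was at 7.21 ± 0.476, 6.60 ± 0.911 and 8.59 ± 1.64 CPM with MSCV, BCR-ABL1 and SFPQ-ABL1. A pair of lines stood apart from their groups. SFPQ-ABL1 line 2 had 4.36 CPM on Abl1 exon 9 and 4.39 on Sfpq exon 9, where lines 1, 3 and 4 had 17.8 to 26.8 and 14.5 to 20.02. BCR-ABL1 line 4 had 3.60 CPM on Sfpq exon 9, where the other BCR-ABL1 lines had 1.53 to 1.98. The same line had 2.21 on Abl1 exon 3, where the others had 3.67 to 4.0, and 20.8 on Abl1 exon 9, where they had 9.23 to 11.8.

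The first comparison asked which genes differ between BCR-ABL1 cells growing without IL-3 and vector cells growing with it, so fusion and IL-3 cannot be separated in it. BCR-ABL1 cells had 349 ± 136 CPM (mean ± SD, n = 4 lines) of Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032) against 27.0 ± 9.35 with MSCV. This gene encodes a pseudokinase and is activated by the stress transcription factor ATF4, and it rose 12.9-fold (log2 fold change 3.69 ± 0.36 SE, adjusted p = 2.71e-05). Pim2 (ENSMUSG00000031155, chromosome X, 7878262 to 7883432), a survival kinase gene and STAT5 target, rose 13.8-fold from 14.9 ± 1.91 to 206 ± 69.8 CPM (log2 fold change 3.79 ± 0.40 SE, adjusted p = 3.94e-05). Cxcr4 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293), a chemokine receptor gene, fell from 432 ± 105 to 87.9 ± 20.9 CPM (log2 fold change -2.30 ± 0.21 SE, adjusted p = 1.77e-05). Among genes past the test whose lines did not overlap between groups, the largest rises included Cox6a2 (213-fold to 7.57 ± 7.98 CPM), the lymphocyte activation marker Cd69 (134-fold to 23.6 ± 14.8) and the receptor gene Gpr141 (132-fold to 10.5 ± 17.0). The others included the hormone gene Fgf23 (111-fold to 16 ± 16.6) and Lcn2 (104-fold to 24.7 ± 29.0), which encodes an iron-binding lipocalin. For Cox6a2, Gpr141, Fgf23 and Lcn2 the SD exceeded the mean, and single lines set the size of these and other rises. Clec4e, Kcnh2, Cpa3, Pf4, Avil, Ctla2a and the endotoxin receptor gene Tlr4 rose 35.1- to 65.8-fold. The largest falls among such genes were in the phosphate transporter gene Slc34a3 (25.5-fold, from 16.8 ± 6.07 to 0.661 ± 0.382 CPM), the retinaldehyde dehydrogenase gene Aldh1a1 (23.5-fold, from 264 ± 172 to 11.3 ± 19.3), Rnf224 (22.6-fold) and Gsta3 (15.6-fold). They were followed by Pik3c2g (13.7-fold, from 1391 ± 559.8 to 102 ± 63.5) and the actin-severing gene Scin (13.0-fold, from 1947 ± 476 to 149 ± 92.7). Mettl7a1, Cmah, Muc6, Elf3, Col9a3 and Gpr160 fell 8.17- to 11.4-fold. Without BCR-ABL1 line 4 the rise was 104-fold for Cox6a2, 53.8-fold for Fgf23, 43.7-fold for Lcn2, 31.2-fold for Avil and 8.46-fold for Ctla2a. The fall was then 162-fold for Aldh1a1, 17.2-fold for Mettl7a1, 18.9-fold for Cmah and 13.1-fold for Gpr160. Leaving out BCR-ABL1 line 2 gave 24.6-fold for Gpr141, of which that line had 35.9 CPM and the other BCR-ABL1 lines 1.75 to 2.22, and 15.8-fold for Cpa3. Without MSCV line 4, the MSCV lines held 1 count of Gpr141 in all, and the folds were 212 for Fgf23, 120.1 for Clec4e, 96.3 for Pf4, 7.39 for Cmah and 9.53 for Gsta3. Cd69 rose 209-fold without MSCV line 1 and Avil 83.6-fold without MSCV line 2. Ctla2a, Gsta3 and Mettl7a1 have close paralogs with which reads can be shared, so their values are uncertain. On gene counts, Abl1 was at 117 ± 6.72 CPM against 97.4 ± 10.8 (adjusted p = 0.0669), Sfpq at 277 ± 47.5 against 278 ± 31.5 (adjusted p = 0.985). Bcr fell from 21.8 ± 0.957 to 18.1 ± 1.31 (adjusted p = 0.0249). In all, 5522 of 17197 genes tested changed (2722 higher and 2800 lower; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Of these, 1551 changed by 2-fold or more. Bcr lost its call without MSCV line 3 (adjusted p = 0.0658) or BCR-ABL1 line 1 (0.0579), 2 (0.0652) or 3 (0.0553), without a filter on low counts (0.0856) and in the fit of 8 libraries (0.0583). In all, 980 genes passed a test against a 1.5-fold change.

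Genes of several signalling and stress groups were higher with BCR-ABL1. Of 24 measured genes of the ATF4 and amino acid response, 23 rose and 1 fell (the serine synthesis gene Psph, named after its values were seen). The counts adjusted over the list alone were 23 and 1 (camera adjusted p = 1.18e-14; adjusted p = 0.359 with an estimated correlation). The cystine transporter gene Slc7a11 rose 4.31-fold to 39.5 ± 5.33 CPM, Sesn2 2.57-fold to 180.4 ± 25.8 and the alanyl-tRNA synthetase gene Aars 3.47-fold to 702 ± 46.6. Of 24 ribosome biogenesis genes, 17 rose, 23 adjusted over the list alone (camera adjusted p = 2.19e-08; adjusted p = 0.420 with an estimated correlation). Examples were nucleolin, Ncl (1.69-fold to 1585 ± 101 CPM), and the helicase gene Ddx21 (2.15-fold to 432 ± 10.1). Among 18 output genes of the ERK pathway, 13 rose, 13 adjusted over the list alone (camera adjusted p = 1.13e-05; adjusted p = 0.359 with an estimated correlation). They included the feedback inhibitor genes Spred1 (2.47-fold), Dusp4 (8.24-fold) and Dusp6 (5.23-fold, from 48.7 ± 10.4 to 255 ± 54.5 CPM). For the STAT5 and IL-3 response, 7 of 15 genes rose, and over the list alone 8 rose and 1 fell (camera adjusted p = 0.00514; adjusted p = 0.359 with an estimated correlation). Cyclin D2, Ccnd2, rose 2.38-fold to 351 ± 15.0 CPM, the STAT5 feedback inhibitor gene Cish 6.96-fold to 216 ± 42.4, and Bcl2l1, which encodes the pro-survival protein BCL-XL, 2.97-fold to 118 ± 18.2. Bcl2l1 is also one of 5 pro-survival BCL-2 family genes of 7 that rose, 5 adjusted over the list alone (camera adjusted p = 0.00896; adjusted p = 0.359 with an estimated correlation). The near-identical Bcl2a1 copies among them are uncertain because reads can be shared between them.

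Of 20 p53 target genes, 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.000808; adjusted p = 0.359 with an estimated correlation). The nuclease gene Aen rose 2.45-fold to 63.6 ± 8.82 CPM and the receptor gene Eda2r 4.80-fold to 46.7 ± 16.1, while Sesn1 fell 2.36-fold to 20.3 ± 3.34. Without SFPQ-ABL1 line 2, 2 p53 target genes fell. Sesn2 is also on the ATF4 list. Among 17 NF-kB target genes, 10 rose, 12 adjusted over the list alone (camera adjusted p = 0.000808; adjusted p = 0.439 with an estimated correlation). Among them were Nfkbiz (3.29-fold to 22.4 ± 7.31 CPM), Relb (6.71-fold to 11.7 ± 5.56) and Nfkb1 (1.73-fold to 218 ± 15.1). Of 15 cytokine genes, 7 rose and 1 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0144; adjusted p = 0.492 with an estimated correlation). Flt3l rose 2.53-fold to 36.3 ± 5.13 CPM and Tgfb1 2.06-fold to 281 ± 33.3, and Tslp fell 4.11-fold to 0.395 ± 0.115, with 2 cytokine genes lower without SFPQ-ABL1 line 4. Cholesterol synthesis and uptake genes moved downward, with 14 of 24 lower, 15 adjusted over the list alone (camera adjusted p = 5.8e-06; adjusted p = 0.359 with an estimated correlation). The reductase gene Dhcr7 fell 2.17-fold to 17.7 ± 2.02 CPM and the sterol sensor gene Insig1 2.31-fold to 27.5 ± 5.11. Of 8 measured T and NK cell genes, 5 fell and 1 rose (Il2rb, named after its values were seen), or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00896; adjusted p = 0.359 with an estimated correlation). Their levels were low, such as 2.03 ± 1.02 CPM of Tcf7 with MSCV and 0.11 ± 0.0722 with BCR-ABL1. The call on that list was lost without MSCV line 4 (adjusted p = 0.0604) or without SFPQ-ABL1 line 1 (0.0716), 2 (0.0618), 3 (0.0512) or 4 (0.0652).

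Markers of granulocytes, mast cells, erythroid cells and fibroblasts changed with BCR-ABL1 without a call on their lists. Of all genes tested, 32.1% changed in this comparison. Of 14 granulocyte and monocyte genes 2 rose and 5 fell (camera adjusted p = 0.483). Ms4a3 was at 223 ± 68.2 CPM against 574 ± 162 and the lysozyme gene Lyz2 at 15.1 ± 4.30 against 32.7 ± 8.61. Of 13 mast cell, basophil and eosinophil genes 3 rose and 4 fell (camera adjusted p = 0.408). Fcer1g was lower at 4.84 ± 0.752 against 13.8 ± 2.73 CPM and the carboxypeptidase gene Cpa3 was higher at 13.1 ± 19.5 against 0.209 ± 0.165. Of 17 erythroid and megakaryocyte genes 2 rose and 4 fell (camera adjusted p = 0.899). The platelet factor gene Pf4 reached 6.88 ± 4.29 CPM and the erythroid factor gene Klf1 fell from 57.4 ± 15.3 to 21.7 ± 8.41. Only 4 fibroblast and stromal genes were measured, of which the collagen gene Col5a1 fell from 979 ± 199 to 236 ± 75.6 CPM (camera adjusted p = 0.408). Without MSCV line 3 or 4 or BCR-ABL1 line 2, 3 or 4, 3 granulocyte genes fell, and without MSCV line 2, 3 or 4, 1 mast cell gene rose. Of the erythroid genes 2 fell without MSCV line 4. Among signalling lists without a call, 7 of 26 ABL adaptors, Src-family kinases and negative regulators rose and 4 fell (camera adjusted p = 0.119). Examples were Rin1 (3.94-fold higher), Dok2 (2.04-fold higher) and the phosphatase gene Ptpn6 (3.58-fold lower). Of 14 FOXO-activated genes 1 rose and 4 fell (camera adjusted p = 0.408), and of 26 oxidative phosphorylation genes 2 fell (camera adjusted p = 0.408). Without MSCV line 1 or 2, BCR-ABL1 line 1 or 3 or SFPQ-ABL1 line 3, 1 oxidative phosphorylation gene fell, and 4 rose without MSCV line 2. Of 24 G2 and mitosis genes, 7 fell, such as Cdc20 (153 ± 12.5 to 107 ± 5.91 CPM) and Ccnb2 (231 ± 26.7 to 145 ± 22.4). The list (camera adjusted p = 0.0650) passed without MSCV line 1 (0.00804), MSCV line 2 (0.0162) or BCR-ABL1 line 1 (0.0340). The camera test called 10 of 26 lists with the preset correlation of 0.01. With an estimated correlation it called 0, with 1 at an unadjusted p under 0.05. The fry test, which tests a list by itself, called 17. The median, the mean and the test differed in sign for the pro-death, interferon, mast cell and erythroid lists. Among all 26 lists, 21 genes stood on more than 1 list and 16 pairs of lists shared a gene, at most 4 (NF-kB targets and cytokines).

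The second comparison set SFPQ-ABL1 cells growing without IL-3 against vector cells growing with it, with the same confounding. Cish (ENSMUSG00000032578, chromosome 9, 107296026 to 107302784) rose 5.74-fold from 31 ± 5.14 to 178 ± 84.5 CPM (mean ± SD, n = 4 lines; log2 fold change 2.52 ± 0.30 SE, adjusted p = 0.00640). The suppressor of cytokine signalling gene Socs1 rose 3.35-fold from 5.60 ± 2.41 to 18.8 ± 6.87 (adjusted p = 0.0266), and Pim2 3.13-fold from 14.9 ± 1.91 to 46.6 ± 25.1 (adjusted p = 0.0432). The gene of the IL-3 receptor alpha chain, Il3ra (ENSMUSG00000068758, chromosome 14, 14346275 to 14356011), fell from 85.3 ± 5.34 to 57.5 ± 3.54 CPM (log2 fold change -0.57 ± 0.09 SE, adjusted p = 0.0115). Genes with the largest rises and lines that did not overlap were the calcium-binding protein gene S100g (416-fold to 11.9 ± 14.7 CPM), Nlrp6 (126-fold to 12.3 ± 8.58), Slco1a5 (43.2-fold to 31.9 ± 17.4), Rnase6 (40.3-fold to 11.8 ± 8.14) and Slfn2 (6.50-fold to 54.2 ± 25.5). Serpina3g, the insulin receptor substrate gene Irs2, B3gnt7, Socs1, Gab3 and the Ikaros family gene Ikzf4 rose 2.69- to 5.21-fold. Without MSCV line 1 the MSCV lines held 2 counts of S100g in all, Slfn2 was 9.98-fold and Serpina3g 8.10-fold higher. S100g was 177-fold higher without SFPQ-ABL1 line 3, Rnase6 69.1-fold without MSCV line 2 and Slco1a5 69.9-fold without MSCV line 4. In these fits Rnase6 and Slco1a5 lost their calls (adjusted p = 0.0518 and 0.0507). Serpina3g and Slco1a5 are uncertain because of close paralogs. The largest falls among such genes were in annexin A1, Anxa1 (4.17-fold, from 29.2 ± 8.10 to 7.02 ± 5.26 CPM), S100a6 (3.62-fold, from 223 ± 95.4 to 61.6 ± 19.3), Tubb4a (3.36-fold), Gnb4 (2.69-fold) and Glp1r (2.68-fold). Next were the immediate early genes Ier2 (2.41-fold, from 82.5 ± 16.2 to 34.3 ± 6.43) and Junb (2.27-fold, from 46.1 ± 6.93 to 20.3 ± 6.38). Anxa1 was 6.26-fold lower without SFPQ-ABL1 line 2. Gelsolin (Gsn), Ypel3, Fgl2, Col5a1 and Fxyd5 fell 2.05- to 2.18-fold. Abl1 was at 121 ± 13.8 CPM against 97.4 ± 10.8 (adjusted p = 0.134), Bcr at 22.1 ± 0.718 against 21.8 ± 0.957 (adjusted p = 0.935) and Sfpq at 359 ± 50.5 against 278 ± 31.5 (adjusted p = 0.174). In all, 308 genes changed (140 higher and 168 lower; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Of these, 106 changed by 2-fold or more. Without normalization factors 210 were higher and 114 lower (64.8% higher, against 45.5%).

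The number of genes called with SFPQ-ABL1 depended on the tool and on single libraries. DESeq2 called 1098, limma-voom 1439 and the fit of the 8 libraries compared 110. The glmTreat test against a 1.5-fold change called 0, with 531 at an unadjusted p under 0.05. Without MSCV line 2, 3 or 4 the count was 84, 33 or 84. Without BCR-ABL1 line 3 it was 168, and without SFPQ-ABL1 line 1, 2, 3 or 4 it was 108, 467, 128 or 71. Of 36 genes that the rule picked and the test called, 5 (Cish, Fxyd5, Glp1r, Ikzf4 and Il3ra) still passed without any 1 library. Of the rest, 8, 27, 31 and 26 were lost without MSCV line 1, 2, 3 and 4 (adjusted p up to 0.0765, 0.109, 0.142 and 0.0998). Without BCR-ABL1 line 1, 2, 3 and 4, 4, 4, 8 and 5 were lost (up to 0.0639, 0.0622, 0.0700 and 0.0625). Without SFPQ-ABL1 line 1, 2, 3 and 4, 16, 1, 19 and 27 were lost (up to 0.138, 0.0540, 0.114 and 0.12). With both SFPQ-ABL1 line 2 and BCR-ABL1 line 4 left out, an alternative chosen after seeing the data, 498 genes changed. In that fit Pim2 lost its call (adjusted p = 0.0640). Among the calls that ended in the fit of 8 libraries were those of Slfn2, Serpina3g, Irs2, Socs1, Gab3, Anxa1, Tubb4a, Gnb4, Junb, Gsn, Ypel3, Fgl2, Pim2, Nfkb1, Selplg, Cd33, Mpo, Fcer1g and Gata2. Their adjusted p ran from 0.0514 for Selplg to 0.103 for Gata2. S100g lost its call with limma-voom (adjusted p = 0.154). Gab3 and Mpo lost theirs with upper-quartile factors (0.0519 and 0.0507), and Fcer1g and Gata2 without normalization factors (0.0600 and 0.0562).

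Several lists lay higher relative to the other genes with SFPQ-ABL1 although few or no members passed singly. Of 15 STAT5 and IL-3 response genes 3 rose (Cish, Socs1 and Pim2), 5 adjusted over the list alone (camera adjusted p = 0.0161; adjusted p = 0.385 with an estimated correlation). Of 24 cholesterol synthesis and uptake genes 1 rose (Acat2, 1.52-fold to 64.0 ± 6.07 CPM, uncertain because of its close copy Acat3), with 3 adjusted over the list alone (camera adjusted p = 0.00191; adjusted p = 0.385 with an estimated correlation). The ribosome biogenesis list was higher (median log2 fold change 0.35, camera adjusted p = 8e-06; adjusted p = 0.440 with an estimated correlation). edgeR called 0 of its 24 genes, also adjusted over the list alone, with 9 higher at an unadjusted p under 0.05, 1 by DESeq2 and 4 by limma-voom. The S phase list was higher (median 0.28, camera adjusted p = 3.52e-05; adjusted p = 0.440 with an estimated correlation). edgeR called 0 of its 24 genes, also over the list alone, with 9 higher at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma-voom. The ATF4 and amino acid response list was higher (median 0.33, camera adjusted p = 0.0150; adjusted p = 0.544 with an estimated correlation). Of its 24 genes edgeR called 0, also over the list alone, with 7 higher and 2 lower at an unadjusted p under 0.05, 1 by DESeq2 and 7 by limma-voom. Of 18 genes of paraspeckles, the nuclear bodies that SFPQ helps to build, 1 rose, 2 adjusted over the list alone (camera adjusted p = 0.00824, and 0.385 with an estimated correlation). The list holds Sfpq itself, on which reads of the fusion are taken to fall, so part of its shift can come from those reads. It also holds the non-coding RNA gene Neat1, and Hnrnpa1 and Nudt21, whose values are uncertain because of processed pseudogenes. The pro-survival BCL-2 list was higher (median 0.39, camera adjusted p = 0.0277; adjusted p = 0.385 with an estimated correlation). Of its 7 genes edgeR called 0, with 2 adjusted over the list alone, 3 higher at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma-voom. Without MSCV line 1, edgeR called 7 ribosome biogenesis, 6 ATF4 and 2 cholesterol genes higher. It called 2 cholesterol genes and 1 pro-survival gene higher without SFPQ-ABL1 line 2, and 1 pro-survival gene without BCR-ABL1 line 4. The single cholesterol and paraspeckle calls were lost without MSCV line 2, 3 or 4 or SFPQ-ABL1 line 1, 3 or 4. Of the STAT5 genes 1 rose without MSCV line 2, 3 or 4 or SFPQ-ABL1 line 3 or 4. Among these lists, the STAT5 list lost its call without MSCV line 2 (adjusted p = 0.0817) or SFPQ-ABL1 line 4 (0.0665). The pro-survival list lost it without MSCV line 1 (0.0727), MSCV line 2 (0.0538) or SFPQ-ABL1 line 4 (0.0787), as did the ATF4 list without MSCV line 2 (0.112), MSCV line 4 (0.0693) or SFPQ-ABL1 line 4 (0.0918).

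Other lists lay lower with SFPQ-ABL1. Of 25 interferon-stimulated genes 1 fell (Irf7, from 9.85 ± 1.95 to 5.05 ± 0.729 CPM), 8 adjusted over the list alone (camera adjusted p = 0.00188; adjusted p = 0.385 with an estimated correlation). Of 23 adhesion and migration genes 1 fell (Selplg, the P-selectin ligand gene, from 81.3 ± 12.1 to 45.0 ± 8.93 CPM), 4 adjusted over the list alone (camera adjusted p = 0.00191; adjusted p = 0.385 with an estimated correlation). Of 18 cytokine receptor and JAK-STAT genes 1 fell (Il3ra), and over the list alone 1 fell and 1 rose (camera adjusted p = 0.0117; adjusted p = 0.385 with an estimated correlation). Of 8 measured early B-lineage genes 1 fell (the B-cell receptor component Cd79a, from 93.4 ± 4.05 to 58.1 ± 7.18 CPM), 2 adjusted over the list alone (camera adjusted p = 0.0278; adjusted p = 0.385 with an estimated correlation). The p53 target list was lower (median -0.18, camera adjusted p = 0.00824; adjusted p = 0.385 with an estimated correlation). Of its 20 genes edgeR called 0, with 5 adjusted over the list alone, 7 lower at an unadjusted p under 0.05, 4 by DESeq2 and 4 by limma-voom. The pro-death BCL-2 list was lower (median -0.35, camera adjusted p = 0.0238; adjusted p = 0.385 with an estimated correlation). Of its 7 genes edgeR called 0, with 3 adjusted over the list alone, 4 lower at an unadjusted p under 0.05, 2 by DESeq2 and 2 by limma-voom. Bbc3 and Bax stand on both of the last lists. The glycolysis list was lower (median -0.19, camera adjusted p = 0.0469; adjusted p = 0.697 with an estimated correlation). Of its 20 genes edgeR called 0, also over the list alone, with 3 lower at an unadjusted p under 0.05, 0 by DESeq2 and 4 by limma-voom. Of 14 granulocyte and monocyte genes 2 rose (myeloperoxidase, Mpo, from 11 ± 5.95 to 45.1 ± 23.4 CPM, and Cd33). Of 13 mast cell genes 2 fell (Fcer1g, from 13.8 ± 2.73 to 8.35 ± 1.04, and Gata2, from 1524 ± 133 to 955 ± 268). Neither list was called (camera adjusted p = 0.773 and 0.398). Without MSCV line 1, 2 interferon-stimulated and 3 adhesion genes fell, and without BCR-ABL1 line 4, 3 interferon-stimulated and 2 early B-lineage genes. The single calls on these 3 lists were lost without MSCV line 2 or 3 or SFPQ-ABL1 line 4, those of Irf7 and Selplg also without SFPQ-ABL1 line 1, and those of Irf7 and Cd79a without MSCV line 4. Without SFPQ-ABL1 line 2, 1 p53 target gene and 2 glycolysis genes fell, and without SFPQ-ABL1 line 1, 1 receptor gene rose. At most 1 granulocyte gene rose and 1 mast cell gene fell without any 1 line other than SFPQ-ABL1 line 2. The pro-death list lost its call without MSCV line 2 (adjusted p = 0.0668) or SFPQ-ABL1 line 4 (0.0502), and the receptor list without SFPQ-ABL1 line 1 (0.131). For the early B list this held without MSCV line 2 (0.0608), MSCV line 4 (0.0588), SFPQ-ABL1 line 2 (0.0537) or SFPQ-ABL1 line 4 (0.0665). The glycolysis list lost it without MSCV line 2, 3 or 4 (0.0927, 0.161, 0.0876), BCR-ABL1 line 2, 3 or 4 (0.0563, 0.0560, 0.0591) or SFPQ-ABL1 line 1, 3 or 4 (0.549, 0.0665, 0.0787). Camera called 14 of 26 lists, 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry 4. Camera called 8 without SFPQ-ABL1 line 4 and 9 without MSCV line 2. The median, the mean and the test differed in sign for the ABL adaptor, granulocyte, mast cell and erythroid lists.

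Genes called in both comparisons with MSCV moved mostly the same way. Of 57 genes higher with both fusions, Cish, Pim2 and Nfkb1 were examples, and of 114 lower with both, Il3ra, Selplg, Cd79a, Col5a1 and Fcer1g. With BCR-ABL1, Il3ra fell to 44.5 ± 4.28 CPM, Selplg to 26.7 ± 4.80 and Cd79a to 42.5 ± 7.05. Another 13 genes moved in opposite directions. Both comparisons use the same MSCV libraries and share their chance values. In 20 simulations all 12 libraries, the controls included, were drawn from the MSCV means without any change. These simulations gave at most 1 call per comparison, so they give no chance value for the overlap of calls. Independent lists of these lengths share 22.2 higher and 27.4 lower genes. With the MSCV libraries split 2 and 2, genes called the same way had a median of 10.5 (range 0 to 110) over 6 splits. Genes called in opposite directions had a median of 2.5 (range 0 to 21). Across the 17197 genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.358. The median was 0.50 in the simulations and 0.216 with split controls. The covariance was 0.145 against 0.0511 simulated, a difference of 0.0935. The overlap of 171 genes became 598 with DESeq2, 811 with limma-voom, and 67 in fits of 8 libraries. Without MSCV line 2, 3 or 4 it was 51, 22 or 48. Without BCR-ABL1 line 3 it was 88, and without SFPQ-ABL1 line 1, 3 or 4 63, 79 or 41. With SFPQ-ABL1 line 2 and BCR-ABL1 line 4 left out, the correlation was 0.177.

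The comparison that the study's title names set both fusions against each other, with all 8 lines grown without IL-3. SFPQ-ABL1 cells had 35.9 ± 15.1 CPM of Trib3 against 349 ± 136 with BCR-ABL1 (mean ± SD, n = 4 lines). This was 9.75-fold less (log2 fold change -3.28 ± 0.35 SE, adjusted p = 0.000104). Rin1 (ENSMUSG00000024883, chromosome 19, 5050481 to 5057071), which encodes a Ras effector that activates ABL kinases, was 4.18-fold lower at 5.15 ± 0.820 against 21.5 ± 4.74 CPM (log2 fold change -2.06 ± 0.18 SE, adjusted p = 4.56e-05). Dhcr7 (ENSMUSG00000058454, chromosome 7, 143823145 to 143848410), which encodes the reductase of the last step of cholesterol synthesis, was 2.37-fold higher at 41.8 ± 6.0 against 17.7 ± 2.02 CPM (log2 fold change 1.24 ± 0.13 SE, adjusted p = 9.24e-05). Among called genes whose lines did not overlap, the largest differences in favour of SFPQ-ABL1 were Plxdc1 (41.0-fold, 14.6 ± 9.01 CPM), Nlrp6 (26.9-fold, 12.3 ± 8.58), and Ston2 (26.6-fold, 33.1 ± 20.04). Next were Rnase6 (26.4-fold, 11.8 ± 8.14) and Aldh1a1 (25.8-fold, 289 ± 187). Muc6, the lymphocyte receptor gene Slamf1, Rnf224, the receptor kinase gene Mst1r, Slc34a3, Mettl7a1 and Scin were 11.1- to 22.3-fold higher. The size and order of several of these rested on BCR-ABL1 line 4. That line held 1.81 CPM of Nlrp6, where BCR-ABL1 lines 1 to 3 had 3 counts in all. Without it the difference was 74.3-fold for Plxdc1, 200.6-fold for Ston2, 65.2-fold for Rnase6, 178-fold for Aldh1a1, 40.6-fold for Slamf1 and 19.7-fold for Mettl7a1. Those in favour of BCR-ABL1 were Gpr141 (684-fold lower with SFPQ-ABL1, at 0.0138 ± 0.0184 against 10.5 ± 17.0 CPM), the lectin receptor gene Clec4e (165-fold, 0.0883 ± 0.102 against 14.8 ± 8.37) and Pf4 (59.6-fold). They were followed by Fgf23 (54.2-fold), Cox6a2 (48.2-fold) and the chemokine receptor gene Ccr1 (37.3-fold). Cd69, Clec4d, Lcn2, Avil, osteopontin (Spp1) and the costimulatory receptor gene Tnfrsf9 were 23.2- to 30.1-fold lower. Leaving out BCR-ABL1 line 2 gave 129-fold for Gpr141, which had 4 counts in the SFPQ-ABL1 lines together, 23.7-fold for Ccr1 and 12.4-fold for Tnfrsf9. Leaving out SFPQ-ABL1 line 2 left 1 count of Gpr141 with SFPQ-ABL1, and the folds of Clec4e and Ccr1 were 381 and 93.1. Cox6a2, Fgf23, Avil and Lcn2 were 23.3-, 26.3-, 15.2- and 11.1-fold lower without BCR-ABL1 line 4. Without SFPQ-ABL1 line 4, Cd69, Clec4d, Cox6a2 and Tnfrsf9 were 46.6-, 53.9-, 78.8- and 43.9-fold lower. Spp1 was at 16.9 ± 9.38 against 424 ± 299 CPM. Abl1 was at 121 ± 13.8 against 117 ± 6.72 CPM (adjusted p = 0.775), Sfpq at 359 ± 50.5 against 277 ± 47.5 (adjusted p = 0.0625) and Bcr at 22.1 ± 0.718 against 18.1 ± 1.31 (adjusted p = 0.0226). In all, 4471 genes differed (2268 higher and 2203 lower with SFPQ-ABL1; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 1314 by 2-fold or more. Without normalization factors 2841 were higher and 1750 lower. Bcr lost its call without BCR-ABL1 line 1, 2 or 3 (adjusted p = 0.0560, 0.0651 and 0.0544) or SFPQ-ABL1 line 1 or 3 (0.0522 and 0.0676), and without a filter on low counts (0.0756). Sfpq passed without BCR-ABL1 line 4 (adjusted p = 0.0414), with upper-quartile factors (0.0474), without normalization factors (0.0288) and with pseudogene counts added (0.0433). In all, 727 genes passed a test against a 1.5-fold change.

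The ATF4 and cholesterol lists differed between the fusions in most members. Of 24 ATF4 and amino acid response genes 23 were lower with SFPQ-ABL1 and 1 higher (Psph, named after its values were seen), with 23 and 1 adjusted over the list alone (camera adjusted p = 2.6e-14; adjusted p = 0.217 with an estimated correlation). The seryl-tRNA synthetase gene Sars was at 258 ± 41.5 against 669 ± 70.3 CPM and the stress factor gene Ddit3 at 20.5 ± 7.42 against 135 ± 32.8. Of 24 cholesterol synthesis and uptake genes 18 were higher, 20 adjusted over the list alone (camera adjusted p = 5.48e-11; adjusted p = 0.217 with an estimated correlation), among them Dhcr7. Fdps and Idi1, also higher, are uncertain, since 89.0% and 66.7% of the counts on them and their processed pseudogenes lay on the pseudogenes. Of 20 p53 target genes 14 were lower and 1 higher, or 16 and 2 adjusted over the list alone (camera adjusted p = 8.3e-07; adjusted p = 0.230 with an estimated correlation). Examples were the pro-death gene Bbc3 (3.79-fold lower at 23.9 ± 5.82 CPM), Eda2r (5.38-fold lower) and Zmat3 (2.50-fold lower). Of 18 ERK output genes 11 were lower, 11 adjusted over the list alone (camera adjusted p = 8.3e-07; adjusted p = 0.439 with an estimated correlation). Among them were Ier2 (2.98-fold, 34.3 ± 6.43 against 102 ± 26.5 CPM), Spred1 (1.75-fold) and Fos (9.05-fold, 3.27 ± 2.37 against 29.5 ± 10.9). Of 17 NF-kB target genes 8 were lower, 8 adjusted over the list alone (camera adjusted p = 0.000104; adjusted p = 0.561 with an estimated correlation). Examples were Nfkbiz (3.17-fold) and Nfkbia (3.95-fold, 14.0 ± 4.07 against 55.1 ± 29.2 CPM). Of 24 ribosome biogenesis genes 7 were lower, 7 adjusted over the list alone (camera adjusted p = 0.000503; adjusted p = 0.749 with an estimated correlation). Pes1 was at 111 ± 13.0 against 144 ± 8.53 CPM. Only 2 ribosome biogenesis genes were lower without SFPQ-ABL1 line 3 and 4 without line 4, and without SFPQ-ABL1 line 2, 2 p53 target genes were higher.

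Of 20 glycolysis genes 5 were lower with SFPQ-ABL1, 7 adjusted over the list alone (camera adjusted p = 0.0420; adjusted p = 0.787 with an estimated correlation). Phosphoglycerate kinase, Pgk1, was at 204 ± 48.1 against 349 ± 36.1 CPM. The number of lower glycolysis genes was 8, 1, 1 and 3 without BCR-ABL1 line 1, 2, 3 and 4, and 2, 9, 1 and 1 without SFPQ-ABL1 line 1, 2, 3 and 4. The call on the list was lost without MSCV line 2 (adjusted p = 0.0707) or 4 (0.0553), BCR-ABL1 line 2 (0.113), 3 (0.0557) or 4 (0.0791) or SFPQ-ABL1 line 1 (0.211). Of 8 T and NK cell genes 5 were higher and 1 lower (Il2rb), or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0420; adjusted p = 0.478 with an estimated correlation). All were at low levels, such as Cd5 at 0.525 ± 0.190 against 0.0938 ± 0.0384 CPM. The number of higher T and NK cell genes was 3, 2 and 3 without BCR-ABL1 line 1, 3 and 4, and 2 without SFPQ-ABL1 line 3. The call on this list was lost without normalization factors (adjusted p = 0.0639) and without SFPQ-ABL1 line 2 and BCR-ABL1 line 4 together (0.0671). It was also lost without MSCV line 1, 2, 3 or 4 (0.105, 0.133, 0.117, 0.105), BCR-ABL1 line 2 or 3 (0.106, 0.0584) and SFPQ-ABL1 line 1, 2, 3 or 4 (0.129, 0.209, 0.101, 0.187). Camera called 8 of 26 lists, 0 with an estimated correlation (3 at an unadjusted p under 0.05), and fry 10. Camera called 13 without BCR-ABL1 line 1. The median, the mean and the test differed in sign for the FOXO, interferon, adhesion, mast cell and fibroblast lists.

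Lists without a call between the fusions also held genes that differed, as did 26.0% of all genes tested. The shares in the STAT5, pro-survival and S phase lists lay near this value. With SFPQ-ABL1, 3 of 15 STAT5 and IL-3 response genes were lower, also adjusted over the list alone (camera adjusted p = 0.0659), among them Ccnd2 (2.15-fold) and Pim2 (4.42-fold). Without MSCV line 2 or SFPQ-ABL1 line 2, 1 gene of this list was higher. Of 7 pro-survival genes 2 were lower, also over the list alone (camera adjusted p = 0.0958), with Bcl2l1 2.26-fold lower. Of 26 genes of ABL adaptors, Src-family kinases and negative regulators 10 were lower and 4 higher, or 10 and 5 over the list alone (camera adjusted p = 0.0958), and Ptpn6 was among the higher ones (2.97-fold). Of 23 adhesion and migration genes 5 were higher and 3 lower, or 6 and 3 over the list alone (camera adjusted p = 0.758), with Cxcr4 2.84-fold higher and the integrin gene Itgal 8.75-fold lower. Of 25 interferon-stimulated genes 6 were higher and 4 lower, or 8 and 4 over the list alone (camera adjusted p = 0.917), with Stat2 1.60-fold higher and Oas2 3.06-fold lower. Only 2 ABL adaptor and 3 interferon-stimulated genes were higher without BCR-ABL1 line 3 or SFPQ-ABL1 line 3 or 4, and 3 adhesion genes without BCR-ABL1 line 2 or 3 or SFPQ-ABL1 line 3 or 4. Of 24 S phase genes 5 were higher and 1 lower, with the same counts over the list alone (camera adjusted p = 0.118). The lower one was the ribonucleotide reductase gene Rrm2 (2.02-fold), and 3 were lower without SFPQ-ABL1 line 2. Of 14 granulocyte and monocyte genes 4 were higher and 1 lower, or 6 and 1 over the list alone (camera adjusted p = 0.461). Mpo was 8.64-fold and Prtn3 4.50-fold higher, and the single lower call was lost without BCR-ABL1 line 2. Camera called the STAT5 list lower without BCR-ABL1 line 1 (adjusted p = 0.0364) or 2 (0.0368), SFPQ-ABL1 line 3 (0.0362) or 4 (0.0169) and without normalization factors (0.0424). Without BCR-ABL1 line 1 or SFPQ-ABL1 line 4 it called the pro-survival list lower (0.0224 and 0.0343) and the S phase list higher (0.0187 and 0.0256). By fry the adjusted p was 0.0196 for the STAT5, 0.0196 for the pro-survival and 0.00164 for the ABL adaptor list. The direction of the interferon list by camera turned without BCR-ABL1 line 3 (adjusted p = 0.911), SFPQ-ABL1 line 4 (0.805) or normalization factors (0.946), and that of the adhesion list without SFPQ-ABL1 line 3 (0.984) or 4 (0.918).

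**Figure D1:**
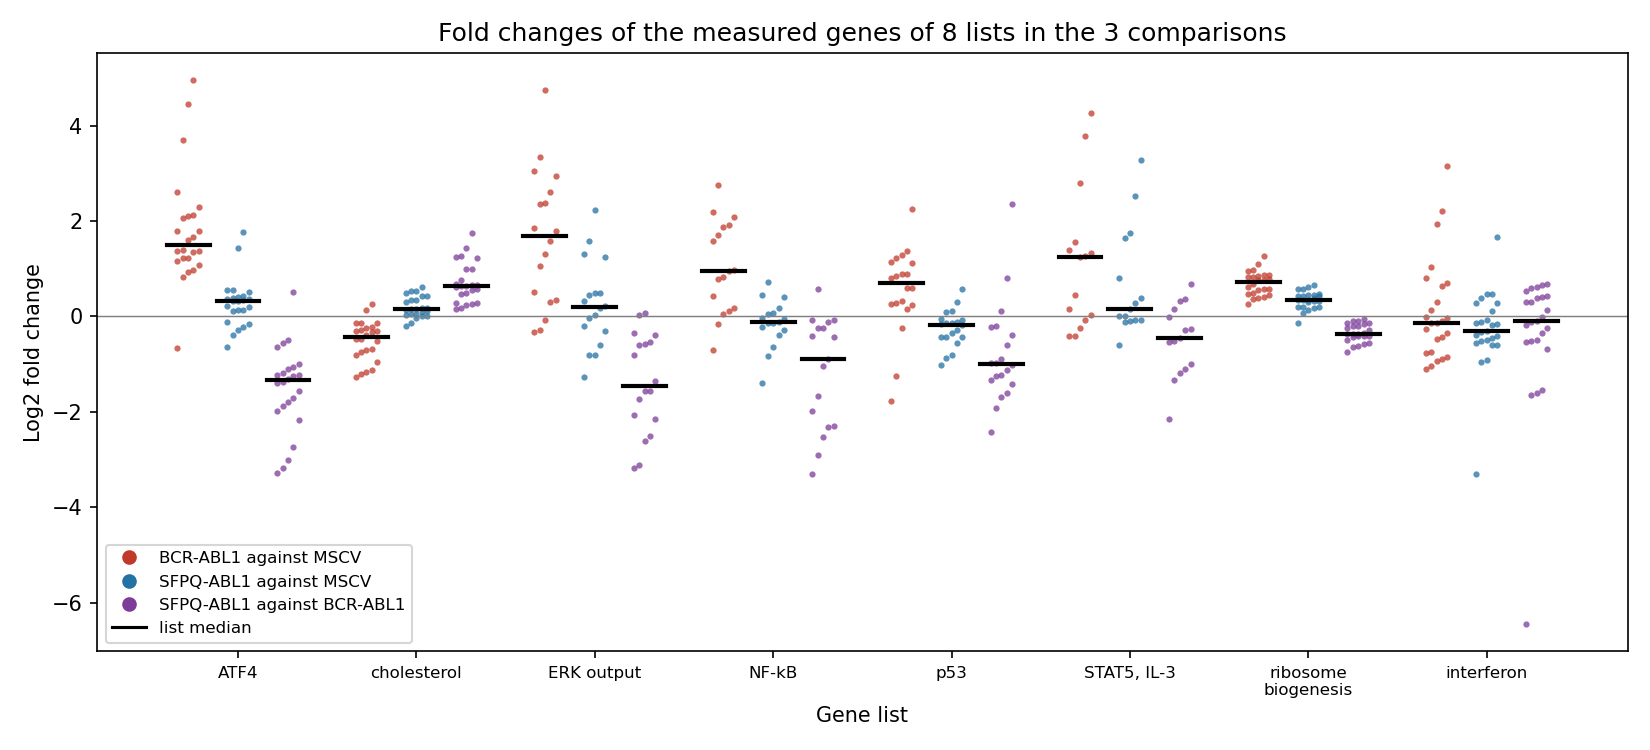
Log2 fold change of each measured gene (point) of 8 fixed gene lists in the 3 comparisons, with a bar at the list median. The ATF4 list has medians of 1.5, 0.33 and -1.34 for BCR-ABL1 against MSCV, SFPQ-ABL1 against MSCV and SFPQ-ABL1 against BCR-ABL1, and the cholesterol list -0.43, 0.15 and 0.64.

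**Figure D2:**
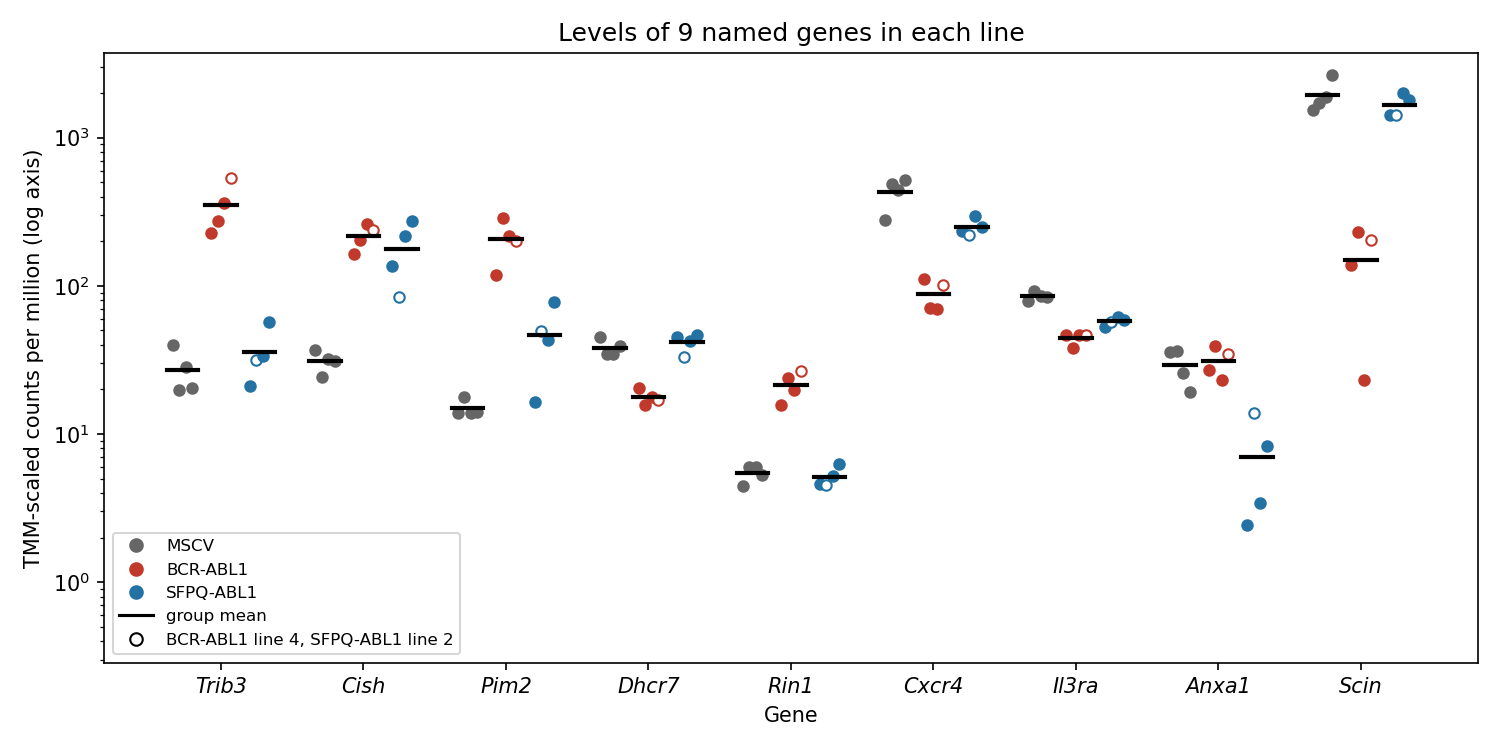
Normalised CPM (log axis) of 9 named genes in each of the 12 lines, with a bar at the group mean and open points for SFPQ-ABL1 line 2 and BCR-ABL1 line 4. Trib3 lies at 27.0 CPM with MSCV, 349 with BCR-ABL1 and 35.9 with SFPQ-ABL1, and Cish at 31, 216 and 178.

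Exon usage was compared in the same 3 ways. Abl1 differed in all of them, most on exon 9 against MSCV (log2 change relative to the gene 4.32 with BCR-ABL1 and 4.54 with SFPQ-ABL1, edgeR adjusted p = 3.23e-29 and 1.35e-31). Between the fusions the exon at 31778921 to 31779024 differed most (-2.80, adjusted p = 5.18e-18). Bcr differed with BCR-ABL1 (exon 1, 1.85, adjusted p = 9.73e-07 against MSCV). Sfpq differed with SFPQ-ABL1 (exon at chromosome 4, 127035808 to 127035854, -2.11, adjusted p = 1.23e-06 against MSCV). In CPM that Sfpq exon ran from 0.198 to 0.448 with SFPQ-ABL1 and from 0.354 to 1.46 with MSCV, so the lines overlapped. The change of -2.11 is relative to a gene whose exon 9 was at 14.0 CPM with SFPQ-ABL1 and 1.84 with MSCV. It therefore does not by itself show loss of an exon of mouse Sfpq. Outside Abl1, Bcr and Sfpq, an exon of Ubp1 (chromosome 9, 113966235 to 113966289) was higher relative to the gene with both fusions, at 0.797 ± 0.415 CPM with BCR-ABL1 and 0.793 ± 0.485 with SFPQ-ABL1 against 0.164 ± 0.0269 with MSCV (edgeR adjusted p = 5.71e-05 and 9.79e-05). With BCR-ABL1, exons of Wdr25 (chromosome 12, 108897909 to 108898725, 0.746 ± 0.0356 against 0.496 ± 0.104 CPM, edgeR adjusted p = 0.000454) and Stard9 (chromosome 2, 120695744 to 120705580, 0.251 ± 0.137 against 0.0423 ± 0.0374 CPM, adjusted p = 0.00329) were higher relative to their genes. Between the fusions, an exon of Nfix (chromosome 8, 84726469 to 84726605) was lower relative to the gene with BCR-ABL1, at 0.106 ± 0.0227 against 0.477 ± 0.140 CPM with SFPQ-ABL1 (edgeR adjusted p = 0.00370). With MSCV this exon was at 0.491 ± 0.251 CPM, and it was also lower relative to the gene with BCR-ABL1 than with MSCV (edgeR adjusted p = 0.00329). In all, 19 genes passed for BCR-ABL1 against MSCV, 6 for SFPQ-ABL1 against MSCV and 13 between the fusions, of 9875 tested (edgeR diffSpliceDGE, Simes p, Benjamini-Hochberg adjusted). Gm20721 and Gnas, both among the 6, were called on the same exon (chromosome 2, 174345990 to 174346057). Its level was 3.94 ± 0.402 CPM with SFPQ-ABL1 against 2.30 ± 0.552 with MSCV, and the same reads count for both genes. In simulated data with known changes, 17 of 126, 8 of 108 and 8 of 111 calls of this test were false in the same order of comparisons. Single genes outside Abl1, Bcr and Sfpq are therefore uncertain. The Ubp1 call with SFPQ-ABL1 was lost with limma diffSplice (adjusted p = 0.266). The Nfix call between the fusions was lost without BCR-ABL1 line 3 (0.12) or SFPQ-ABL1 line 4 (0.0669), and that against MSCV passed in 15 of 17 alternatives. The count became 31 for BCR-ABL1 against MSCV without BCR-ABL1 line 1. It became 22, 5, 7 and 8 between the fusions without MSCV line 2, BCR-ABL1 line 3 and SFPQ-ABL1 lines 1 and 3.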

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

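The comparison of spreads corrected for error, the ratio of the Sfpq exons and the share of the SFPQ-ABL1 level in BCR-ABL1 lines 1 to 3 were tests chosen only after the result was seen, as was the choice to look at SFPQ-ABL1 line 2 and BCR-ABL1 line 4. Within each group of 4 lines, a line was singled out where its gap to the nearest other line took most of the range of the group. This happened for 17 of 402 groups of values, and chance gives about 1 in 20 groups, or 20.1.

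SFPQ-ABL1 line 2 stood apart in 5 values, the most of any line. It had 193 CPM of Ccnd2 where the other SFPQ-ABL1 lines had 152 to 155, and 1356 of Gata2 where they had 797 to 854. Its level of the protease gene Prtn3 was 59.2 CPM against 244 to 313, of Cd33 0.104 against 0.462 to 0.523, and of Stat2 44.6 against 57.6 to 59.7. SFPQ-ABL1 line 1 had 11.9 CPM of Fgl2 against 22.2 to 24.6, and 0.737 of Tubb4a against 2.25 to 2.36. BCR-ABL1 line 2 had 35.9 CPM of Gpr141 against 1.75 to 2.22 in the other BCR-ABL1 lines. It had 185 of Dok2 against 254 to 269 and 38.1 of Il3ra against 46.3 to 46.9. In BCR-ABL1 line 4 the mitochondrial share of counts was 2.06% against 1.74 to 1.78%, Fxyd5 196 CPM against 158 to 164, and Nlrp6 1.81 against 0 to 0.0270. BCR-ABL1 line 1 had 9.73 CPM of Ypel3 against 8.15 to 8.37. Among the vector lines, MSCV line 1 had 76.8 CPM of Spred1 against 65.9 to 67.3. MSCV line 2 had 17.7 of Pim2 against 13.8 to 14.2, and MSCV line 4 had 0.322 of Gpr141 against 0 to 0.0134.

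Against MSCV, 5522 genes changed with BCR-ABL1 and 308 with SFPQ-ABL1. A larger spread between the SFPQ-ABL1 lines was argued against as the whole cause by the SD of the log2 fold changes after removal of their error, which was at least 0.726 for BCR-ABL1 and at most 0.472 for SFPQ-ABL1 over the fits without 1 library. Without SFPQ-ABL1 line 2 the SFPQ-ABL1 count was 8.27% of the BCR-ABL1 count, against 5.58% with it, which argues against that line as the whole cause. With every library thinned to 59355018 counts the ratio of both counts was 17.4 against 17.9, which argues against depth. A difference in the activity or protein amount of the fusions may lie behind the pattern and was not tested, while the means on Abl1 exon 9, which both fusions hold, gave no sign of less SFPQ-ABL1 transcript (17.5 ± 9.50 against 13.3 ± 5.14 CPM, with 4.36 in SFPQ-ABL1 line 2 and 17.8 to 26.8 in the others).

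BCR-ABL1 line 4 had 3.60 CPM on Sfpq exon 9, which the SFPQ-ABL1 lines have at raised levels, and 2.21 on Abl1 exon 3, where the other BCR-ABL1 lines had 3.67 to 4.0, and 20.8 on Abl1 exon 9, where they had 9.23 to 11.8. Higher expression of mouse Sfpq alone was argued against, since exon 9 over exon 10 was 1.82 times its geometric mean in the 7 other lines without SFPQ-ABL1 (95% prediction interval 1.27 to 2.63). Over 41 genes with at least 5 CPM that were at least 10 times higher in SFPQ-ABL1 lines 1, 3 and 4 than in BCR-ABL1 lines 1, 2 and 3, line 4 held a median of 10.2% of the SFPQ-ABL1 level (95% bootstrap interval 8.32 to 12.5), against 11.7% on Sfpq exon 9 (95% interval for counting error 8.81 to 14.8), while BCR-ABL1 lines 1, 2 and 3 held 1.20%, 0.662% and -0.450% by the same rule set against the others of these 3 lines (over 43, 42 and 38 genes). The bootstrap interval treats these genes as independent. The shares were uneven, with 25 genes above the lower bound of the exon share, while Scin, the most abundant, had 4.62% and Muc6 4.25%. Scin, Muc6, Aldh1a1 and others were also among the largest falls from MSCV to BCR-ABL1. Their share therefore cannot tell SFPQ-ABL1 material from a level nearer that of MSCV. Among those called higher with SFPQ-ABL1 than with MSCV were Nlrp6 (12.5%), Rnase6 (7.63%), S100g (1.08%) and Mpo (-0.987%). On Abl1 exon 2, line 4 had 0.881 CPM, the other BCR-ABL1 lines 0.314 to 0.379 and the SFPQ-ABL1 lines 0.145 to 0.248. On Abl1 exons 4 and 7 it had 1.63 and 1.94 CPM, where the other BCR-ABL1 lines had 0.894 to 0.962 and 0.935 to 1.35. SFPQ-ABL1 cells or library mixed into line 4 stay open as a hypothesis. A share of this size would not raise Abl1 exon 2, and would neither raise Abl1 exon 9 nor lower Abl1 exon 3 that far. Those values remain unexplained.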

How the results depend on the processing

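The fit without SFPQ-ABL1 line 2 and BCR-ABL1 line 4 together, the fit with pseudogene counts added to parent genes, and most alternatives for the overlap and the correlation were tests chosen only after the result was seen. Among the genes named in the text, most of them called, 1842 values without 1 library kept their direction and side of the threshold, 179 lost the call and 1 gained it, and under the other alternatives 1762 kept both, 80 lost and 6 gained the call. Among all genes that the rule picked, 5 of 8, 55 of 87 and 4 of 9 without a call gained one in some alternative, in the order of the comparisons. For gene lists the values that kept both, lost and gained the call were 563, 45 and 15 without 1 library, and 255, 47 and 12 otherwise. The cause of the changes below was not tested unless stated. For SFPQ-ABL1 against MSCV, 308 genes became 1098 with DESeq2, 1439 with limma-voom and 110 in the 8 libraries compared. The count was 498 without both lines named above, 0 against a 1.5-fold change (531 unadjusted, edgeR glmTreat), and 33 to 467 without 1 library. Against that fold 980 genes passed for BCR-ABL1 against MSCV and 727 between the fusions. The overlap of 171 genes became 598, 811, 67 and 0 in the same order of tools, where glmTreat called 0 genes in one comparison, and 22 to 241 without 1 library. The correlation of 0.358 was 0.177 without both lines. With an estimated correlation 0 lists were called in each comparison, with 1, 1 and 3 at an unadjusted p under 0.05, and fry called 17, 4 and 10. Without 1 library 8 to 14 lists were called for SFPQ-ABL1 against MSCV and 6.0 to 13 between the fusions. Exon usage counts were 325, 24 and 63 with the gene-level F test, 31 for BCR-ABL1 against MSCV with limma, and 14 to 31 for BCR-ABL1 against MSCV and 5.0 to 22 between the fusions without 1 library.

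Replicate numbers were tested as a replicate block although they were not shown to pair the lines. Of 12 same-number pairs, 7 correlated over 0.1 in their deviations. The median was 0.200 for same-number pairs and -0.0791 for pairs of different number. Of 12 libraries, 9 correlated best with their own number. This is a hint from the data and not the design. The block gave 6307, 726 and 5336 genes in the order of the comparisons and an overlap of 416.

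Directions turned in 27 values of 9 results, each with an adjusted p of 0.542 or more in the alternative. The log2 fold change of Sfpq for BCR-ABL1 against MSCV was 0.00286 with DESeq2, 0.0918 with limma-voom, 0.00153 with pseudogene counts added, and -0.0886 to 0.101 without 1 library. That of Bcr for SFPQ-ABL1 against MSCV was -0.00675 with upper-quartile factors and -0.00799 to 0.0425 without 1 library, and that of Abl1 between the fusions was -0.00482 to 0.113 without 1 library. The granulocyte list for SFPQ-ABL1 against MSCV had an adjusted p of 0.991 without normalization factors and 0.125 to 0.927 without 1 library. For BCR-ABL1 against MSCV the erythroid list had 0.983 without both lines and 0.496 to 0.990 without 1 library, the oxidative phosphorylation list 0.130 to 0.680 and the fibroblast list 0.399 to 0.978. Between the fusions the interferon list had 0.946 without normalization factors and 0.636 to 0.990 without 1 library, and the adhesion list 0.636 to 0.985. The cause was not tested.

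As for depth, thinning every library to 59355018 counts, the total of the shallowest, left 5457, 313 and 4341 genes called, against 5522, 308 and 4471. In simulated data the gene test missed most changes of 1.5-fold, recovering 37.3%, 31.3% and 26.9% of them in the order of the comparisons, so a missing call does not exclude a difference of that size.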

Other observations

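In this part the fit without SFPQ-ABL1 line 2 and BCR-ABL1 line 4 and the splits counted without Abl1, Bcr and Sfpq were tests chosen only after the result was seen. Several interferon-stimulated, adhesion, early B-lineage and cytokine receptor genes were lower with BCR-ABL1 than with MSCV. Of all genes tested, 32.1% changed in this comparison, in either direction. Of 25 interferon-stimulated genes 9 fell and 2 rose, or 9 and 4 adjusted over the list alone, without a call on the list (camera adjusted p = 0.132). Only 1 rose without MSCV line 4 or BCR-ABL1 line 2 or 4, and 4 rose without BCR-ABL1 line 1 or SFPQ-ABL1 line 1 or 3. The immunoproteasome genes Psmb8 (171 ± 14.3 to 79.8 ± 12.8 CPM, mean ± SD, n = 4 lines) and Psmb9 (80.6 ± 3.32 to 39.3 ± 6.71) and the peptide transporter gene Tap1 (101 ± 11.3 to 52.4 ± 6.0) were among those that fell (edgeR adjusted p = 5.45e-05, 5.45e-05 and 0.000374). Of 23 adhesion and migration genes 9 fell and 2 rose, with the same counts over the list alone (camera adjusted p = 0.102). The integrin gene Itgal rose 5.93-fold to 48.5 ± 7.54 CPM and Itga5 fell from 155 ± 7.52 to 79.5 ± 7.32. Of 8 measured early B-lineage genes 4 fell, 4 adjusted over the list alone with 1 higher (camera adjusted p = 0.118), such as Cd79b (49.6 ± 5.50 to 20.5 ± 3.79 CPM). Of 18 cytokine receptor and JAK-STAT genes 9 fell and 3 rose, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.0549), such as the erythropoietin receptor gene Epor (35.6 ± 4.89 to 17.5 ± 5.28 CPM) and Stat5b (168 ± 13.7 to 110.5 ± 11.2). The receptor list passed without MSCV line 1 (adjusted p = 0.0443), MSCV line 2 (0.0272), BCR-ABL1 line 2 (0.0355) or BCR-ABL1 line 4 (0.0427), and without SFPQ-ABL1 line 2 and BCR-ABL1 line 4 together (0.0416).

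The 8 libraries of each comparison can be split into 4 and 4 in 35 ways, and the counts were made again in fits of those 8 libraries. For genes, the real split gave the largest count in all 3 comparisons, which argues against chance. With 35 splits the share of splits as large cannot fall under 1 in 35, so chance is not excluded. The real split gave 5117 genes for BCR-ABL1 against MSCV and the highest other 0, with 110 and 1 for SFPQ-ABL1 against MSCV and 4453 and 2 between the fusions. In each case 1 split, the real one, gave a count as large. In fits of all groups, the gene count for SFPQ-ABL1 against MSCV ran from 33 to 467 without 1 library. For gene lists called by camera, the real split of SFPQ-ABL1 against MSCV gave 13 lists and the highest other 11, with 1 split as large. This margin lay inside the range of the count without 1 library, 8 (without SFPQ-ABL1 line 4) to 14 in fits of all groups, with 9 without MSCV line 2. Camera with an estimated correlation called 0 of 26 (1 at an unadjusted p under 0.05) and fry 4, so chance is left open for this count. Chance could not be excluded for BCR-ABL1 against MSCV, where 5 of 35 splits gave at least the real 10 lists and the highest other gave 11. The same held between the fusions, where 21 splits gave at least the real 7 and the highest other gave 12. For exon usage, the real split gave 11 genes and the highest other 6 for BCR-ABL1 against MSCV, 6 and 5 for SFPQ-ABL1 against MSCV, and 22 and 6 between the fusions. The real counts include genes among Abl1, Bcr and Sfpq, on whose exons reads of the fusions are taken to fall, so they are raised by the design. Without these genes, the real split gave the most genes for BCR-ABL1 against MSCV (9, highest other 6) and between the fusions (20, highest other 5). In each, 1 split was as large. In fits of all groups, the count over all genes between the fusions ran from 5 to 22 without 1 library. In simulated data 17 and 8 calls of this test were false for these comparisons, so chance is left open for both counts. Chance could also not be excluded for SFPQ-ABL1 against MSCV, where 5 of 35 splits gave at least the real 4 genes and the highest other gave 5.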
